A study of Arabidopsis thaliana with 4 samples.

How the data were processed

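Total RNA of 5 d old seedlings was labelled with Cy3 or Cy5 and hybridised to 4 two-colour Agilent arrays, each holding the hsfb1 hsfb2b double mutant and the wild type of 1 replicate, with the dyes exchanged between replicates 1 and 3 and replicates 2 and 4, per the labels. The scanner files come from Agilent Feature Extraction 9.1.3.1, per the submitters' processing notes and the file headers. Their spot and local background values are intensity values in arbitrary units, deposited without normalization (median pixel brightness per spot, per the file headers). Feature Extraction's processed signals are intensity values after its background subtraction and dye normalization, per the file headers. The deposited log10 ratio of red over green was computed by Feature Extraction from those processed signals. The deposited series values were found to be the natural log of mutant over wild type, from their correlation of 0.987 to 0.999 in absolute size with the scanner ratios on the same array and from their slopes, whose signs followed the dye of the mutant. Their scale and direction are thus settled, while their centring is not given in the sources used here, and the column medians for replicates 1 to 4 were 0.0458, 0.0813, 0.107 and -0.0011 in natural log units. The files gave 1 slide and 1 scan for all 4 arrays, so neither could be tested as a batch.

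Median signals were used in place of the mean signals that had been planned, because the files used here carried median signals. Background was corrected with normexp at an offset of 50, ratios were normalized within arrays by loess with control and outlier-marked spots at weight 0, and spots that Feature Extraction had marked as outliers were left out (190 to 399 of 37685 non-control spots per array). The offset draws the ratios of dim genes towards 0, so large ratios such as those of the mutated genes are compressed. Replicate spots were averaged (23 probes had 10 spots each), which left 37478 probes. Of these, 26236 carried a locus name for 25665 loci, and 11242 carried none and were kept out of the gene tests. Probes were kept where they were well above background in all 4 mutant channels or all 4 wild-type channels and had at least 3 ratios, with the brightest probe per gene used. This gave 19314 genes, of which 19217 matched a locus in the RefSeq table of assembly TAIR10.1, used for symbols and gene order. Another 112 genes passed the brightness filter but lost too many ratios to outlier marks. Probes of 2 of the 377 genes with several tested probes passed the threshold in opposite directions. For 16 genes the probe was not well above background on any array of one genotype, so their ratios are bounds, and none of these is named here.

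The log2 ratio of red over green was fitted per gene in limma 3.58.1 (R 4.3.3) with a gene-wise dye effect and the genotype coded by dye, followed by eBayes and Benjamini-Hochberg adjustment, two-sided, at 0.05. The array paired the genotypes. Errors are standard errors from this fit. The dye effect passed the same threshold for 3503 genes. Across genes, which are not independent replicates, ratios turned to mutant over wild type correlated at 0.80 between arrays of the same dye orientation and at 0.35 to 0.49 between orientations. The differences between arrays 1 and 3 and between arrays 2 and 4 were nearly uncorrelated across genes (r = -0.0053).

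The 14 gene lists were fixed before the data were examined and covered the HSF family without HSFB1 and HSFB2B, small heat shock proteins, large chaperones with other classical heat-induced genes, endoplasmic reticulum stress, jasmonate and ethylene defence, salicylic acid defence, the circadian clock, oxidative stress, light harvesting and carbon fixation, abscisic acid with dehydration and cold, warm-temperature growth and auxin, cell division, root tissue markers, and seed storage and germination markers. Each was set against the other genes with camera (preset correlation 0.01, on z-scores of the moderated statistics, two-sided, adjusted over the 14 lists). Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, used the members with complete ratios, and the estimated correlations rest on few residual degrees of freedom. With the estimated correlation no list passed (adjusted p from 0.47 to 0.69). That test takes its reference from the same few degrees of freedom, so it has little power and a lost call decides little. The estimated correlations of warm-temperature growth and auxin (-0.24) and oxidative stress (-0.0066) were below the preset 0.01. A higher correlation was thus not what removed those calls. The other lost calls had higher estimates, 0.36 for small heat shock proteins, 0.38 for large chaperones and 0.57 for endoplasmic reticulum stress. Light harvesting had 0.45, root markers 0.25 and jasmonate and ethylene defence 0.22. If such correlations are real, the camera p-values of these lists at the preset correlation are too small. Fry gave an adjusted p of 0.031 for both heat lists, 0.00086 for warm-temperature growth and auxin, 0.043 for jasmonate and ethylene defence, 0.029 for oxidative stress, 0.064 for endoplasmic reticulum stress, 0.051 for root markers and 0.17 for light harvesting. Fry also passed for the HSF family (0.049), the clock (0.029) and cell division (0.033), and gave 0.99 for salicylic acid defence, 0.12 for abscisic acid and 0.22 for seed markers.

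The genes named were set by a rule fixed before the data were examined: both mutated genes, the 8 largest ratios in each direction among changed genes that went the same way on all 4 arrays, the 2 measured members of each list with the smallest p, and every changed HSF or small heat shock protein gene. Genes outside this rule are marked where they appear. Alternatives covered background correction, offset, within-array and between-array normalization, the deposited series values, the brightness filter, the dye effect, the probe rule, each replicate left out, array weights (statmod 1.5.0 was used by the separate-channel fit), a robust and trended eBayes, and a separate-channel fit. Keeping outlier-marked spots, centring the series values and following the 2-fold count under each alternative were added after seeing the data.

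The fit was tested on simulated ratios for 18644 genes with the dye effects of the real comparison and 200 seeded genes. Noise was drawn independently per gene, with the real residual spreads shuffled over genes. The fit recovered 8% of genes changed by 0.2 on the log2 scale, 38% at 0.3, 88% at 0.6 and 92% at 1, with 3 false calls among 116. The seeded share was far below the share called in the real data. The adjusted threshold was thus stricter, and these rates do not carry over. In the list test, 3.2% of 1000 unshifted random lists of 15 genes had an unadjusted p under 0.05. Those genes were simulated independently, so this rate does not cover lists of co-regulated genes.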

Results

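Transcript levels were compared between hsfb1 hsfb2b double mutant and wild-type Arabidopsis thaliana seedlings of the Col-0 background after mild heat. HSFB1 and HSFB2B encode class B heat shock factors, which bind heat shock promoter elements but lack the activation domain of class A factors and are known as transcriptional repressors. Seedlings were 5 d old, had been grown at 23 °C and were harvested after 30 min at 32 °C. Each of the 4 two-colour oligonucleotide arrays held labelled RNA of both genotypes from the same plate, and the 4 arrays were biological replicates per the labels. The mutant was labelled with Cy3 on replicates 1 and 3 and with Cy5 on replicates 2 and 4. Median spot signals were 120.5 to 136 units in the green channel and 166 to 204 in the red, against median local backgrounds of 46 to 47 and 56 to 56.5. Between 58.7% and 60.9% of non-control spots were well above background in each channel, and no spot was saturated. The number of arrays, 4, limits the precision of every ratio below. Unheated seedlings were not analysed here, so the ratios compare the genotypes in heat and do not measure how far either genotype responded to it.

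Both mutated genes were far lower in the double mutant on every array. HSFB1 (AT4G36990) had a log2 ratio of mutant over wild type of -5.79 ± 0.03 (SE, n = 4 arrays), which is 55.4-fold lower (limma adjusted p = 2.2e-10), with single arrays between -5.84 and -5.72. HSFB2B (AT4G11660) was 25.6-fold lower, at -4.68 ± 0.07 (limma adjusted p = 1.7e-07), with single arrays between -5.12 and -4.38. In the centred series values HSFB1 and HSFB2B stood at -6.38 and -6.22, the lowest of any alternative run. Both probes stayed well above background in the mutant channel of all 4 arrays. The position of each probe relative to its mutation was not given in the sources used here, so the remaining signal has no assignment to a part of the transcript.

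Across the 19314 genes tested, 5747 differed between the genotypes at an adjusted p under 0.05 in limma, 3208 of them higher and 2539 lower in the double mutant. Most differences were small: the median absolute log2 ratio of the changed genes was 0.19, and 32 genes differed at least 2-fold, 21 higher and 11 lower. Heat shock protein and chaperone genes were lower as groups. The lists of warm-temperature growth and auxin (6 measured genes), jasmonate and ethylene defence, oxidative stress and endoplasmic reticulum stress were higher. These group calls came from camera with a preset correlation and were lost with an estimated correlation (adjusted p = 0.47 to 0.53). The latter test rests on few residual degrees of freedom, so the loss decides little. For the heat lists the estimates were 0.36 and 0.38, and their p-values at the preset 0.01 are too small if those hold. The count depended on the gene-wise dye term, without which 1826 genes passed. It also depended on the array normalization (2547 with median centring in place of loess). It fell to 3269 without replicate 1 and 2195 without replicate 3, but was 5814 without replicate 2 and 5165 without replicate 4. Of the changed genes 55.8% were higher, against 45.5% with median centring and 79.6% with the deposited series values uncentred.

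**Figure D1:**
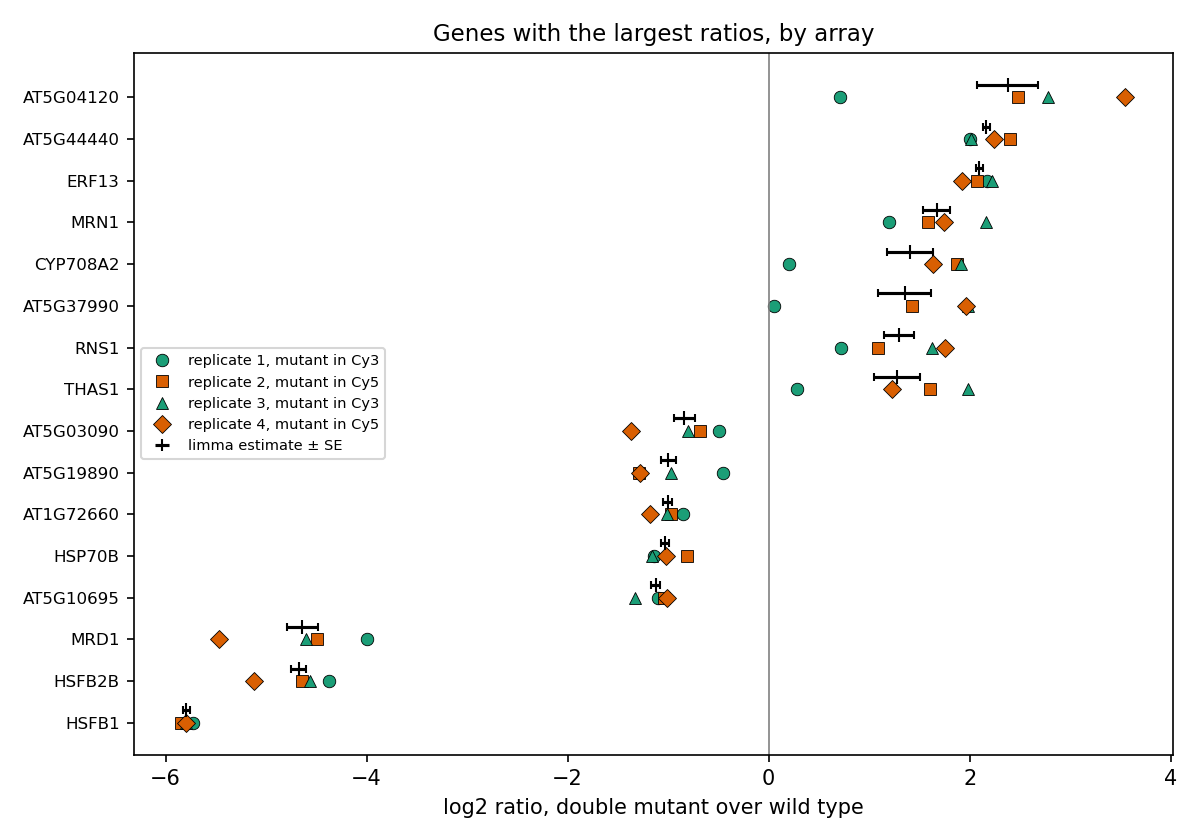
Log2 ratio of double mutant over wild type on each of the 4 arrays for HSFB1, HSFB2B and the genes with the largest ratios in each direction. The latter were taken among changed genes that went the same way on all 4 arrays. Marker shape gives the replicate, colour the dye of the mutant RNA and the black bar the limma estimate with its standard error, and HSFB1 sits between -5.84 and -5.72 on all arrays while AT5G04120 spreads from 0.71 to 3.55.

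Small heat shock proteins, which hold unfolding proteins in a soluble state, were lower as a group in the double mutant. Of 15 measured members, 12 were lower, 1 was higher and 2 did not pass the threshold, with the same counts when p-values were adjusted over the list alone. The list's median log2 ratio was -0.47. The chloroplast protein gene HSP21 was 1.76-fold lower (-0.82 ± 0.05, SE, n = 4 arrays, limma adjusted p = 9.3e-05), and the endoplasmic reticulum member HSP22 was 1.68-fold lower (-0.75 ± 0.04, limma adjusted p = 5.2e-05). The cytosolic members HSP17.6C-CI, HSP17.6A and HSP17.6B-CI had log2 ratios of -0.83, -0.80 and -0.67. HSP17.6II, HSP17.4-CIII and HSP15.7 were lower by smaller amounts, at -0.51, -0.47 and -0.46. The mitochondrial members HSP23.6 and HSP23.5 stood at -0.54 and -0.35, and HSP17.6A-CI and HSP26.5 at -0.36 and -0.25, with 3 arrays measured for HSP17.6II, HSP15.7 and HSP23.5. HSP14.7 was the member that rose, to 0.12 ± 0.03 (limma adjusted p = 0.035), a call lost in the Feature Extraction processed signals (0.12), in the centred series values, with median centring, without the dye term, and without replicate 1 (0.11), replicate 3 (0.13) or replicate 4 (0.10). The list was lower than the other genes by camera with a preset correlation of 0.01 (adjusted p = 1.4e-07), and this call was lost with an estimated correlation (adjusted p = 0.47). Without the dye term the calls of HSP17.6A-CI, HSP17.6B-CI, HSP23.5 and HSP26.5 were lost, that of HSP23.5 also in the series values uncentred (-0.24), and that of HSP26.5 also in the processed signals (-0.22), in the series values uncentred (-0.14) and centred (-0.22), and without replicate 3 (-0.20). With median centring HSP23.5 and HSP26.5 stood at -0.58 and -0.39, and in the series values uncentred HSP17.6A-CI and HSP14.7 stood at -0.22 and 0.20. The array values of HSP17.6A-CI ran from -0.98 with the mutant in Cy3 to 0.24 with the mutant in Cy5. HSP17.6B-CI had means of -1.29 with the mutant in Cy3 and -0.05 in Cy5, and HSP17.6C-CI -1.16 and -0.49. HSP23.5 had -0.66 (1 array) and -0.04. For HSP21 the orientations were close, at -0.86 and -0.77.

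The larger chaperones, co-chaperones and other classical heat-induced genes followed the same direction. Of 31 measured members, 21 were lower, 3 were higher and 7 did not pass, and 23 were lower and 3 higher when adjusted over the list alone. BAG6, a co-chaperone of the BAG family, was 2.28-fold lower (-1.19 ± 0.04, SE, n = 3 arrays, limma adjusted p = 5.2e-05). HSP70B was 2.05-fold lower (-1.03 ± 0.04, n = 4 arrays, limma adjusted p = 2.8e-05). The 3 higher members, named after their values were seen, were the ascorbate peroxidase gene APX2 (0.41 ± 0.04), the mitochondrial HSP70 gene MTHSC70-1 (0.24 ± 0.04, n = 3 arrays) and the DnaJ-type co-chaperone gene AT1G71000 (0.67 ± 0.04, n = 3 arrays). The median was -0.41, and camera with the preset correlation gave an adjusted p of 2.6e-10, against an adjusted p = 0.47 with an estimated correlation. The median was -0.27 in the separate-channel fit. HSP17.4, HSP17.8-CI, HSP18.2, HSP101 and HSC70-1, list members outside the naming rule that were picked after their values were seen, had too few ratios free of outlier marks for the test. With outlier-marked spots kept, the first 4 of these had log2 ratios of -0.61, -0.28, -0.85 and -0.79, each past the threshold, and HSC70-1 had 0.04 ± 0.06.

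Of the remaining heat shock factor genes 19 were measured, and 3 were higher and 1 was lower, in the test over all genes and when adjusted over the list alone, and 15 did not pass. HSFA7B was 1.47-fold higher (0.56 ± 0.03, SE, n = 4 arrays, limma adjusted p = 7.7e-05), and HSFA6B was 1.39-fold higher (0.48 ± 0.06, limma adjusted p = 0.0017). HSFA8 rose slightly, to 0.16 ± 0.03 (limma adjusted p = 0.011). HSFA2, a heat-induced activator of chaperone genes, was 1.12-fold lower (-0.16 ± 0.05, limma adjusted p = 0.038), with a mean of -0.43 with the mutant in Cy3 and 0.11 with the mutant in Cy5. The HSFA2 call was lost in the Feature Extraction processed signals, in the deposited series values, with a normexp offset of 0, without the dye term, and without replicate 3 or 4. Without these replicates the HSFA2 values were -0.10 and -0.13, and HSFA2 stood at -0.10 in the processed signals, at -0.017 in the series values uncentred and at -0.32 with median centring. HSFA6B stood at 1.16 in the processed signals and at 1.24 in the series values uncentred. HSFA8 lost its call in the processed signals, in the centred series values, with median centring, without the dye term and without replicate 3 (0.14). The list's median was 0.04 (camera adjusted p = 0.26, and fry adjusted p = 0.049 towards higher) and turned slightly negative without replicate 3 or 4 (-0.0035 and -0.0049), with 0.03 without replicate 1.

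**Figure D2:**
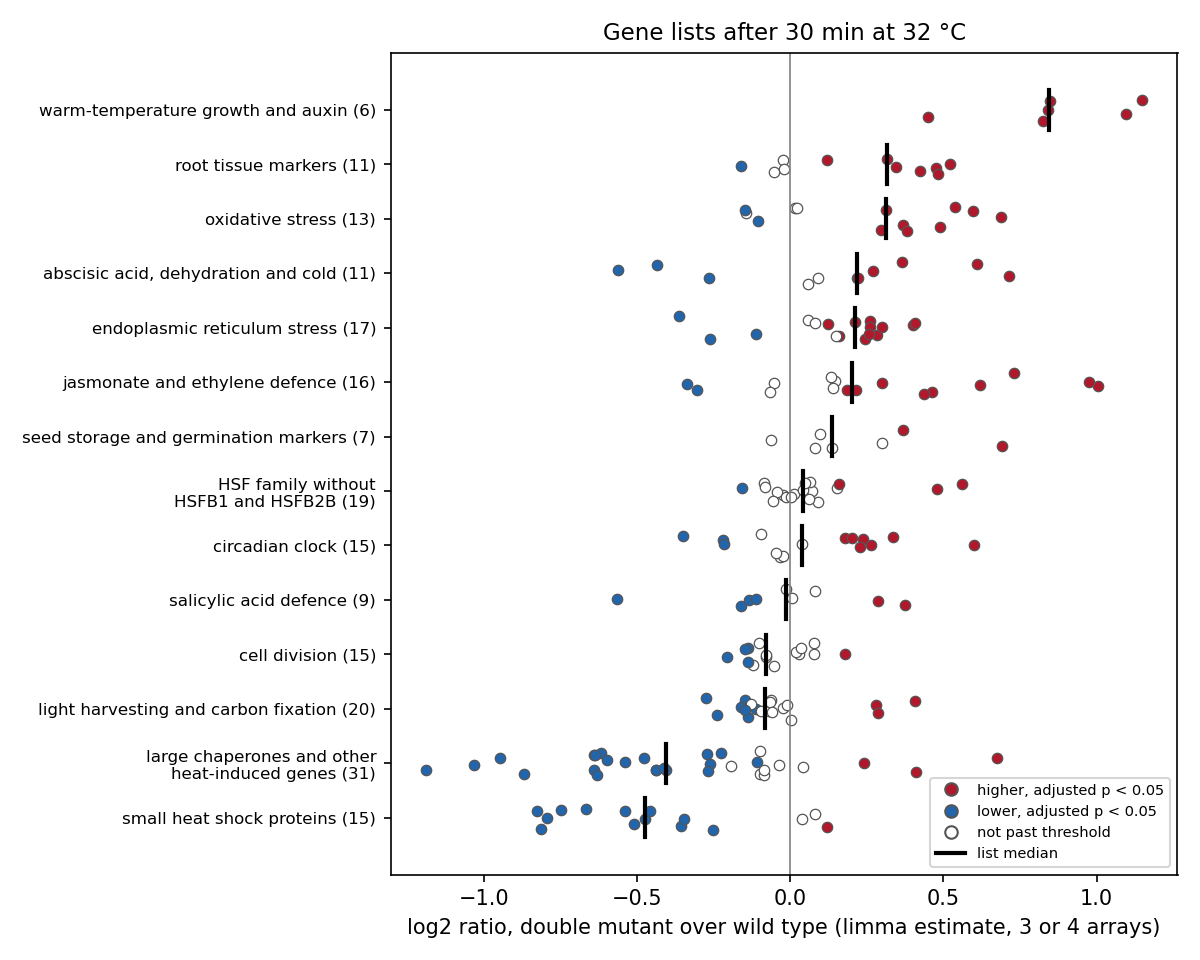
Log2 ratio of double mutant over wild type (horizontal axis) for each measured member of the 14 gene lists, with the number of measured members in brackets, a black bar at each list's median, red points for genes higher and blue for genes lower at an adjusted p under 0.05, and open points for genes that did not pass. The heat lists have medians of -0.47 and -0.41, and the warm-temperature growth and auxin list has a median of 0.84.

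Genes of warm-temperature growth and auxin response were higher throughout their list. All 6 measured members rose, over all genes and when adjusted over the list alone, with a median log2 ratio of 0.84. The auxin-induced repressor genes IAA29 and IAA5 were 2.22-fold and 2.14-fold higher (SE 0.05 and 0.06 on the log2 scale, n = 4 arrays, limma adjusted p = 2.8e-05 and 5.4e-05). Camera with the preset correlation gave an adjusted p of 2.0e-07, and the call was lost with an estimated correlation (adjusted p = 0.47). That correlation was -0.24, and the test had few residual degrees of freedom. IAA5 stood at 1.65 in the series values uncentred. PIF4, the member without enough ratios free of outlier marks, named outside the rule after its values were seen, had a log2 ratio of -0.06 ± 0.03 (limma adjusted p = 0.24) with marked spots kept.

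Jasmonate and ethylene defence genes were higher as a group. Of 16 measured members 9 rose, 2 fell and 5 did not pass, and 11 rose when adjusted over the list alone. JAZ1, a repressor of jasmonate signalling that jasmonate itself induces, was 2.01-fold higher (1.01 ± 0.04, SE, n = 4 arrays, limma adjusted p = 2.2e-05). MYC2, the transcription factor that JAZ proteins bind, was 1.97-fold higher (0.98 ± 0.05, limma adjusted p = 5.4e-05). The members that fell, named after their values were seen, were VSP2 (-0.34 ± 0.06) and LOX2 (-0.30 ± 0.05), both jasmonate-inducible leaf genes. The median was 0.20 (camera adjusted p = 0.0032), and the call was lost with an estimated correlation (adjusted p = 0.47). That median was 0.30 without replicate 2 and without background correction, and 0.54 and 0.63 in the processed signals and the series values uncentred. Salicylic acid defence genes went both ways: of 9 measured, 2 rose and 4 fell over all genes, and 3 rose and 4 fell when adjusted over the list alone. PR5 was 1.48-fold lower (-0.57 ± 0.05, limma adjusted p = 0.00026), and EDS5, a transporter needed for salicylic acid accumulation, was higher (0.38 ± 0.03, limma adjusted p = 0.00039). The list's median was -0.01 (camera adjusted p = 0.60), and it turned positive in the deposited series values uncentred (0.05) and without replicate 3 (0.03) and was -0.06 without replicate 1.

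Oxidative stress genes were higher in the double mutant, with 8 of 13 measured members up, 2 down and 3 not past the threshold, and 8 up and 3 down when adjusted over the list alone. The zinc finger gene ZAT12 was 1.61-fold higher (0.69 ± 0.06, SE, n = 4 arrays, limma adjusted p = 0.00027), and the glutathione transferase gene GSTU25 was 1.51-fold higher (0.60 ± 0.03, limma adjusted p = 7.0e-05). The median was 0.31 (camera adjusted p = 0.0032, and adjusted p = 0.47 with an estimated correlation). Endoplasmic reticulum stress genes also rose, with 11 of 17 higher and 3 lower, and 12 higher and 3 lower when adjusted over the list alone. CNX1, encoding the lectin chaperone calnexin, and BIP2, encoding an endoplasmic reticulum HSP70, were each 1.32-fold higher (0.41 ± 0.04 and 0.40 ± 0.04, limma adjusted p = 0.00049 and 0.00073). The median was 0.21, with a camera adjusted p of 0.0018 and an adjusted p = 0.53 with an estimated correlation, and median centring of the arrays also ended the call (median 0.12, camera adjusted p = 0.14), while the median was 0.33 in the series values uncentred.

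Genes of abscisic acid, dehydration and cold had 6 of 11 measured members higher and 3 lower, over all genes and when adjusted over the list alone. RD29A was 1.64-fold higher (0.71 ± 0.04, SE, n = 4 arrays, limma adjusted p = 9.4e-05), and the dehydrin gene LTI30 was 1.52-fold higher (0.61 ± 0.04, limma adjusted p = 0.00011). The list's median was 0.22 (camera adjusted p = 0.14), and it was 0.10 without replicate 2. Clock genes had 7 of 15 measured members higher and 3 lower in both counts. GRP7, an RNA-binding protein gene under clock control, was 1.52-fold higher (0.60 ± 0.04, limma adjusted p = 0.00013), and the evening gene ELF4 was 1.26-fold higher (0.33 ± 0.03, limma adjusted p = 0.00056). Their list had a median of 0.04 (camera adjusted p = 0.26, and fry adjusted p = 0.029 towards higher), which turned negative with median centring (-0.04) and was 0.07 without replicate 1 and 0.12 without replicate 2 or 3.

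Markers of tissue and stage were measured on the same arrays. Root tissue markers were higher, with 7 of 11 up and 1 down, over all genes and when adjusted over the list alone, and a median of 0.32 (camera adjusted p = 0.011, and adjusted p = 0.47 with an estimated correlation). CASP1, a Casparian strip protein gene, was 1.40-fold higher (0.48 ± 0.03, SE, n = 4 arrays, limma adjusted p = 0.00013), and the root hair expansin gene EXPA18 was 1.27-fold higher (0.35 ± 0.04, limma adjusted p = 0.0010), with 0.64 in the processed signals and 0.73 in the series values uncentred. The list's median was 0.53 in the series values uncentred. The median on single arrays was 0.15 for replicate 1 and between 0.32 and 0.35 for replicates 2 to 4. Light harvesting and carbon fixation genes had 3 of 20 members higher and 8 lower in both counts, with a median of -0.08 (camera adjusted p = 0.015, and adjusted p = 0.55 with an estimated correlation). Their median was -0.53 with the mutant in Cy3 and 0.35 with the mutant in Cy5, and it was -0.28 with median centring, where the call held (camera adjusted p = 0.00028). The list's call was lost in the series values uncentred, where the median turned positive (0.07), in the centred series values, in the processed signals, without the dye term and without replicate 1 (-0.07) or replicate 4 (-0.08). LHCB1.1 and LHCA3 had log2 ratios of -0.27 ± 0.05 and -0.24 ± 0.04 (limma adjusted p = 0.0074 and 0.0055), and the sign differed between the dye orientations for both. Both calls were lost without the dye term and in the series values uncentred, that of LHCA3 also in the processed signals and the centred series values, and with median centring they stood at -0.44 and -0.41. Cell division genes had 1 of 15 members higher and 4 lower in both counts, with a median of -0.08 (camera adjusted p = 0.14, and fry adjusted p = 0.033 towards lower) that turned positive in the uncentred series values (0.0084) and was -0.04 without replicate 1. AUR1, a mitotic kinase gene, stood at -0.21 ± 0.03 (limma adjusted p = 0.0033) and the cyclin gene CYCA1;1 at 0.18 ± 0.03 (limma adjusted p = 0.0074), the latter losing its call without replicate 3 (0.17), with median centring and without the dye term. In the series values uncentred CYCA1;1 stood at 0.31, and AUR1 lost its call there (-0.16) and in the centred ones (-0.24). Seed storage and germination markers had 2 of 7 members higher, or 3 when adjusted over the list alone, and none lower. These were EM6 (0.69 ± 0.11, limma adjusted p = 0.0042) and OLEO2 (0.37 ± 0.10, limma adjusted p = 0.028), with a list median of 0.14 (camera adjusted p = 0.067), and both calls were lost with the robust eBayes setting, that of OLEO2 also without replicate 3 (0.27), in the processed signals (1.04), with a normexp offset of 0 (0.48), in the series values uncentred (1.12) and without the dye term. OLEO2 stood at 0.22 without replicate 4 and at 1.03 in the centred series values, and EM6 at 1.04 in the uncentred ones. The list itself passed without replicate 1 (0.25), replicate 2 (0.19) or replicate 4 (0.19), and its median was 0.08 without replicate 3.

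Among the largest increases, ERF13, an ethylene response factor gene, was 4.28-fold higher (SE 0.04 on the log2 scale, n = 4 arrays, limma adjusted p = 2.2e-07), and AT5G44440 was 4.49-fold higher (2.17 ± 0.04, limma adjusted p = 2.2e-07). AT5G04120 had the highest estimate of the named genes at 2.38 ± 0.30 (limma adjusted p = 0.0015). Its wild-type channel was well above background on 1 of 4 arrays, so the size of its ratio is poorly determined. MRN1, encoding marneral synthase, was 3.18-fold higher (1.67 ± 0.13, limma adjusted p = 0.00021). The thalianol pathway genes CYP708A2 and THAS1 were 2.65-fold and 2.42-fold higher, and AT5G37990 and the ribonuclease gene RNS1 were 2.55-fold and 2.45-fold higher. For CYP708A2, THAS1, AT5G37990, RNS1 and AT5G04120 the arrays differed widely, with replicate 1 lowest in each, and their calls were lost with the robust eBayes setting. AT5G04120 stood at 5.08 in the processed signals and 5.16 in the series values uncentred, and MRN1 at 3.56 and 3.64. In the series values uncentred AT5G37990 and RNS1 stood at 2.18 and 2.01, and AT5G37990 stood at 0.87 without replicate 3.

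Among the largest decreases beyond the mutated genes, MRD1 was 24.9-fold lower (-4.64 ± 0.15, SE, n = 4 arrays, limma adjusted p = 1.6e-05), with single arrays from -5.47 to -4.00, and stood at -6.97 in the processed signals and in the centred series values. AT5G10695 and AT1G72660 were 2.18-fold and 2.00-fold lower (SE 0.04 and 0.05 on the log2 scale, limma adjusted p = 2.7e-05 and 4.5e-05). AT5G19890 was 2.00-fold lower (SE 0.07 on the log2 scale, limma adjusted p = 0.00018) and AT5G03090 had a log2 ratio of -0.84 ± 0.10 (limma adjusted p = 0.0013), the latter well above background on 2 of 4 arrays in the mutant channel. The naming rule required a ratio in the same direction on all 4 arrays, so genes with a missing ratio were passed over too. BAG6, at -1.19 with 3 arrays measured, was left out of this group for that reason. Not all of the 11 genes lower by at least 2-fold are therefore named. AT5G03090 stood at -1.33 without background correction, at -3.38 in the processed signals and at -3.30 in the series values uncentred. The number of genes past 2-fold rose from 32 to 178 in the Feature Extraction processed signals and to 230 in the deposited series values.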

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

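The tests of dye, green tissue, root share and the thalianol and marneral genes below were chosen after the results were seen, while the intensity test and the count over other splits were set before. A check of the 4 arrays for a value standing apart was made for 70 results (named genes and list medians), of which about 1 in 20 stands apart by chance, and 3 did. The CYP708A2 log2 ratio was 0.20 on replicate 1 and 1.63 to 1.91 on the others (gap over range 0.837). The root tissue marker median was 0.15 on replicate 1 and 0.32 to 0.35 on the others (gap over range 0.841). The warm-temperature growth and auxin median was 0.93 on replicate 2 and 0.85 to 0.86 on the others (gap over range 0.871), a difference small beside the median itself. Probes with no locus name, which the report does not use, gave 272 that differed between the genotypes among 1832 tested, 146 higher and 126 lower, and 1 of them was past 2-fold, at -2.45 ± 0.18.

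Heat shock protein and chaperone genes were lower in the double mutant, with a median of -0.43 over the 46 members of both heat lists. Intensity bias shared by genes of the same brightness bin is argued against. The median lay at percentile 0 of 10000 random lists matched on mean intensity in 20 bins, whose central 95% ran from -0.05 to 0.04. A bias confined to the very brightest spots inside the top bin was not tested, and stays open. A dye effect as the whole cause is argued against by the medians of -0.51 with the mutant in Cy3 and -0.29 with the mutant in Cy5. Both bootstrap intervals lay below 0 but resampled genes, so they do not measure the spread between arrays. On single arrays the medians ran from -0.70 to -0.27 for small heat shock proteins and from -0.36 to -0.17 for the large chaperone list. A smaller share of green tissue is argued against by the heat median lying below the green one (-0.342 on the log2 scale). The 95% bootstrap interval, again over genes, was -0.46 to -0.15. With the mutant in Cy3 alone, however, the green median was as low (-0.53). The genotype stays open as a biological explanation, and so does uneven heating, which was not measured, although both genotypes shared a plate in each replicate per the labels.

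Root tissue markers were higher as a list by camera with the preset correlation (adjusted p = 0.011), a call lost with an estimated correlation (adjusted p = 0.47). A larger share of whole root tissue in the mutant samples would raise all 11 markers alike only if each were specific to root. That was not tested here, and 7 of the 11 were higher. Named after their values were seen, these were EXPA7 (0.52), CASP1 (0.48), COBL9 (0.48), PRP3 (0.42), EXPA18 (0.35), RHD6 (0.32) and MYB36 (0.12). The 3 markers SHR, SCR and PLT1 had 95% upper bounds of -0.08, 0.05 and 0.06 against a list median of 0.32. PLT1 was dim (mean log2 intensity 7.79) and counts little, the bound of SHR held under each alternative run, and that of SCR held under each except the fit without the dye term. The bounds thus argue against a larger share of whole root only as far as SHR and SCR are specific to root. The same holds for the higher thalianol and marneral genes, whose own ratios decide nothing here because 3 of the 7 were noticed for their size. A larger root share, a change in part of the root and the genotype itself stay open for both.

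For the number of genes changed, the 4 pairs can be turned in 7 ways that keep dye and genotype apart, too few for a share under 0.05. The real arrangement, 1 of the 7, gave 5747 genes, and the highest of the others gave 0. In those others any genotype difference falls wholly or partly into the residual. Their low counts were thus built in, and no conclusion is drawn from the contrast.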

How the results depend on the processing

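Keeping outlier-marked spots, centring the series values and following the 2-fold count under each alternative were chosen after the results were seen. The log2 ratios of all 56 named genes kept their sign under every alternative that gave them a value, and 38 stayed past the threshold in each. Most were named for large ratios, small p or a passed threshold, so kept signs were likely from the choice itself. The call count of 5747 became 2665 at an adjusted p under 0.01 and 32 with a 2-fold minimum. It was 2547 (1159 higher, 1388 lower) with median centring, where the variances were almost fully pooled over genes (median 37960 total degrees of freedom, against 7.43), 1826 (1242 and 584) without the dye effect and 3618 (2078 and 1540) in the centred series values, and 1210 genes were lower in the uncentred ones. Leaving out a replicate gave 2195 to 5814 genes, 1439 to 3218 higher and 756 to 2596 lower, on fewer residual degrees of freedom. The 2-fold count was 178 in the processed signals, 53 without background correction, and 230 and 188 in the series values uncentred and centred. With an estimated correlation, the list calls were lost at unchanged medians: small heat shock proteins (-0.47), large chaperones (-0.41), endoplasmic reticulum stress (0.21), jasmonate and ethylene defence (0.20), oxidative stress (0.31), light harvesting (-0.084), warm-temperature growth and auxin (0.84) and root markers (0.32). The test with an estimated correlation has little power on so few arrays. The endoplasmic reticulum list lost its call with median centring (0.12). Light harvesting lost its call in the processed signals (-0.012), the series values uncentred (0.069) and centred (-0.0092), and without the dye effect (-0.087), stood at -0.28 with median centring, and had -0.12 to -0.064 with a replicate left out. Seed markers passed without background correction (0.21), with median centring (0.16), in the centred series values (0.57) and without the dye effect (0.14), and had 0.078 to 0.25 with a replicate left out. Except where the setting's own construction shows it, the cause was not tested. The main fit was already paired, because the array pairs the genotypes in every ratio. The separate-channel fit carried that pairing as a correlation between the channels of a spot (0.9626), had no further replicate block and called 7663 genes. Slide and scan as a random block were not run, since all 4 arrays shared 1 slide and 1 scan. Genes close to background, with ratios compressed by the offset, limit what these arrays can show.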

Other observations

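The gene groups in this part were chosen after the results were seen, and the test of the genes next to HSFB1 and HSFB2B was set before. Gene families were formed from the letters that open the RefSeq symbols, giving 200 families with at least 8 measured members, of which 29 passed camera with the preset correlation (Benjamini-Hochberg over the 200). With an estimated correlation none of the 200 passed (adjusted p of at least 0.895), which holds for each of the 6 families named here. That test has little power on so few residual degrees of freedom. Of 25 xyloglucan endotransglucosylase genes (XTH), which remodel the wall during growth, 19 were higher and 1 was lower, with a median log2 ratio of 0.39 (camera adjusted p = 2.0e-08). Of 23 arabinogalactan protein genes (AGP) 17 were higher and 0 lower, with a median of 0.39 (camera adjusted p = 7.5e-07), and of 14 fasciclin-like genes (FLA) 9 were higher and 0 lower (median 0.19, camera adjusted p = 0.0017), against 5 higher without replicate 1 and 4 with median centring or without the dye term. On the same arrays 7 of the 11 root tissue markers were higher, with a median of 0.32. Among regulators, 20 of 51 WRKY genes were higher and 2 lower (camera adjusted p = 0.0053), against 12 higher with median centring and 13 without the dye term. Of 9 JAZ genes 6 were higher and 0 lower (camera adjusted p = 0.010), against 4 higher without replicate 1, without replicate 3 or without the dye term. Of 14 plastid transcription genes named PTAC, 7 were lower and 0 higher (median -0.10, camera adjusted p = 0.017), beside the light harvesting median of -0.08. Without replicate 1 the lower PTAC genes numbered 2, without replicate 3 they numbered 1, with median centring 3, and in the deposited series values or without the dye term 0. The medians of these 6 families kept their sign under the alternatives run, but not their size. That of FLA ran from 0.13 with median centring to 0.36 in the series values uncentred. That of PTAC ran from -0.17 with median centring to -0.0093 in the series values uncentred.

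Genes of the thalianol and marneral pathways, which lie in 2 clusters of neighbouring genes that make root triterpenes, were all higher. The thalianol genes AT5G47980, CYP705A5, CYP708A2 and THAS1 had log2 ratios of 0.93 ± 0.10, 1.14 ± 0.20, 1.40 ± 0.23 and 1.28 ± 0.23 (SE, n = 4 arrays), and the marneral genes CYP705A12, CYP71A16 and MRN1 had 0.64 ± 0.09, 1.09 ± 0.11 and 1.67 ± 0.13. All 7 passed the limma threshold (adjusted p from 0.00021 to 0.0064), and 4 did so with the robust eBayes setting. Their median on single arrays was 0.43 for replicate 1 and 1.55, 1.72 and 1.06 for replicates 2, 3 and 4, so the lowest array was also the lowest for the root markers.

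A hypothesis was that the mutations, or sequence linked to them, may change the genes beside them. The 10 nearest measured genes of each locus, 20 in all, had a median absolute log2 ratio of 0.06, at percentile 30.95 of 10000 pairs of random windows. The largest was 0.33 (TRM10, named after its value was seen), and 4 of the 20 passed the limma threshold, so the test gave no sign of a local effect beyond the array-wide rate. MRD1, which lies on another chromosome than both mutated genes, stood at -4.64 beside -4.68 for HSFB2B, and at -6.97 beside -6.22 in the centred series values, and these data hold no test of why.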
